A study of Bos taurus with 9 samples.

How the data were processed

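Luteal tissue RNA from 9 heifers on 3 diets was measured, with 3 arrays per diet. The diets were endophyte-free fescue seed (EF), endophyte-infected fescue seed (EI), and endophyte-infected seed with domperidone at 1.44 mg per kg body weight (EID). Per the labels, the EF heifers were killed on day 11 after ovulation and the EI and EID heifers on day 14. From EF heifers 2 tissue samples were ground for RNA, and from EI and EID heifers 1. Biotin-labelled cRNA was made by linear amplification and hybridized to CodeLink UniSet Rat I arrays, so bovine RNA was read by probes designed for rat transcripts. The numbers of the arrays fall into separate ranges, one holding the EF and EID arrays and the other the EI arrays, and what the ranges stand for is not given in the sources used here.

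The deposited values are intensities on a linear scale, with background subtracted by the authors and each array scaled so that its median lies between 0.986 and 0.997. The background method, the divisor and the reason for empty cells are not given in the sources used here. The table holds 10399 probes, of which 7281 carry 1 gene symbol, 21 carry several and 3097 carry none. Of the 6437 distinct rat symbols, 6083 (94.5%) also name a gene in the bovine annotation ARS-UCD2.0. The probes' sequences and genome positions are not given in the sources used here, so no match to the bovine transcript could be scored.

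Each array was divided by its own median, values under 0.1 of the median were set to 0.1, and log2 was taken. Among the tested values, 467 of 91530 (0.51%) were raised to that floor. A probe was tested when it had a value on at least 2 arrays of every diet and lay over the floor on at least 3 of the 9 arrays. This left 10177 probes, 7114 of them with 1 gene symbol, and the 222 probes left out all lacked values. Control probes were to be left out but could not be told from the table, so probes without a symbol stayed in the tests.

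The diets were compared with limma 3.58.1 in R 4.3.3. One fit over the 9 arrays with a mean per diet gave moderated two-sided tests with an intensity trend in the variance (lmFit and eBayes) and 6 residual degrees of freedom. Adjusted p-values follow Benjamini and Hochberg over the tested probes of a comparison, and a probe passed at an adjusted p under 0.05. Errors given with log2 changes are standard errors of that fit, and n is 3 arrays per diet unless stated. The p-values measure only the spread between these samples, which may be technical, since the labels state separate heifers but not how their RNA was handled.

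Gene lists fixed before the data were examined, 19 in number, covered steroidogenesis, cholesterol synthesis, luteal hormone and growth factor receptors, prostaglandin metabolism, dopamine, serotonin and adrenergic signalling, endothelium and angiogenesis, extracellular matrix and remodelling, immune cells and cytokines, apoptosis, respiratory chain and ATP synthase, ribosomal proteins, heat shock and ER stress, antioxidant and xenobiotic enzymes, cell cycle and proliferation, smooth muscle and vascular tone, immediate early genes, blood and plasma proteins, follicle and oocyte, and neuronal genes. The neuronal list stood for genes not anticipated in this tissue. Each of the 6273 genes was represented by its brightest probe. Lists were tested with camera (limma) at a preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry, with Benjamini and Hochberg adjustment over the 19 lists.

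The rule for named genes, also fixed beforehand, took probes with 1 symbol that lay over the floor on every array of at least 1 of the compared diets. It named the 12 that rose and the 12 that fell by the largest log2 change among those that passed and whose diets did not overlap, up to 4 members of each list that passed (otherwise the 2 with the smallest p), and 10 genes of luteal function. After the values were seen, the list members named in the comparisons with EI were limited to 2 per list. A background limit per array was set, after the data were seen, at the mode of the intensities plus 2 standard deviations of the values below the mode. Where all arrays of 1 diet lay within it, the change is given as "at least N-fold", the other diet's mean over the mean background limit. No fold is given where both diets lay within it.

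The alternatives tried were floors of 0.05 and 0.25, log2 of the value plus 0.25, quantile normalization, scaling to the 75th percentile, only the brighter part of the probes, no trend in the variance, a 1.5-fold threshold, only the 6 arrays of the diets compared, array weights, a replicate block, and leaving out each array in turn. Cyclic loess normalization, quantile normalization together with the brighter probes, only probes with 1 symbol, and the count of probes that passed under all 4 scalings were added after seeing the data. The correlation over probes of the changes in the comparisons with EI was set against 20 simulations of unchanged groups that share the EI arrays. The median change of a list relative to all genes of the list tests was added after seeing the data.

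The procedure was tested on simulated data in the layout of the EID vs EF comparison with 10177 probes. With nothing put in, it called 0 probes. Changes were put only into probes over the median brightness, so dimmer probes were not covered. It found 29.9% of 67 probes changed 1.5-fold, 64.2% of 67 changed 2-fold and 97% of 66 changed 4-fold, with 3 false calls among the unchanged probes. A gene list shifted by 0.5 on the log2 scale passed, and it was the 1 list that did. The false calls hold for the simulated noise only. Among real probes over 16 times the median, the median standard deviation was 0.117 in EF and 0.0681 in EID on the log2 scale. The real EID vs EF count of 346 fell to 14 without the variance trend. The simulation therefore does not show how many of the 346 are false.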

Results

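The 9 arrays measured transcript levels in the corpus luteum of heifers fed endophyte-free fescue seed (EF), seed infected with the fungal endophyte of tall fescue (EI), or infected seed with the dopamine receptor antagonist domperidone (EID), with 3 heifers per diet. Intensities are given as multiples of the array median, which lies in the background on every array. Probes over the background limit made up 22% to 24% of those on EF and EID arrays and 16.1% to 17.6% on EI arrays. The 75th percentile lay at 2.40 to 2.51 on EF and EID arrays and at 1.63 to 1.66 on EI arrays. Empty cells numbered 181 to 193 on EF and EID arrays and 67 to 71 on EI arrays. The number of arrays limits the precision. Among probes over 16 times the median, the median standard deviation between arrays of a diet was 0.12 in EF, 0.06 in EI and 0.07 in EID on the log2 scale.

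**Figure D1:**
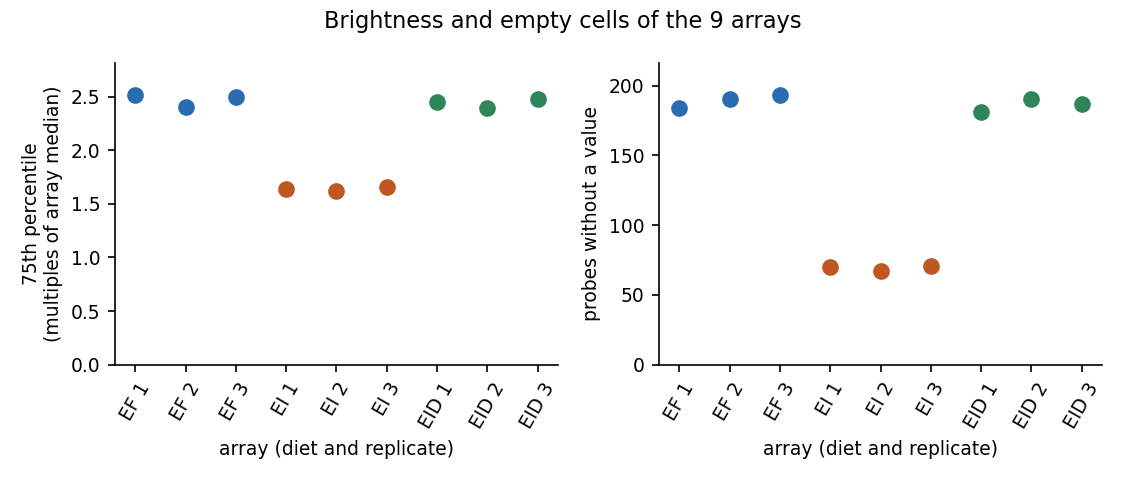
Upper quartile of the intensities (left, multiples of the array median) and number of probes without a value (right) on each of the 9 arrays. The EI arrays lie at 1.63 to 1.66 and 67 to 71, apart from all EF and EID arrays.

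Several genes of luteal function could not be read on these arrays. Star, Hsd3b1, Drd2 and Timp1 were not measured here. Probes for Lhcgr, the luteinizing hormone receptor, Prlr, the prolactin receptor, Ptgfr, the prostaglandin F receptor, Vegfa, an angiogenic factor, and Scarb1, the receptor for high-density lipoprotein, lay within the background on all diets and did not pass in any comparison. Cyp11a1, the enzyme that makes pregnenolone from cholesterol, read 2.69 in EF, 2.25 in EI and 4.53 in EID. Of 56 neuronal genes, 36 averaged within the background, while Gabra5, a GABA receptor subunit, read 72.7 in EF and Kcna2, a potassium channel, read 127. Lists of genes anticipated in this tissue did not all read above it more often. Within the background lay 21 of 29 steroidogenesis genes, 40 of 50 immune genes and 35 of 45 respiratory chain genes, but 9 of 26 ribosomal proteins.

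Against EF, the EI arrays read Ccl27, a chemokine, at least 32.2-fold higher (0.97 in EF, 91.3 in EI; limma adjusted p = 1.8e-13). Grhpr, a glyoxylate reductase, rose from 3.15 to 21.9 (log2 change 2.80 ± 0.15 SE, n = 3 per diet). Hs3st1, a heparan sulfate sulfotransferase, fell from 22.2 to 3.70, a log2 change of -2.59 ± 0.11, and Fos, an immediate early transcription factor, fell from 135 to 29.6, a change of -2.19 ± 0.09. Pdia3, a protein disulfide isomerase, rose from 290 to 633 (1.13 ± 0.07) and Ptgds, a prostaglandin D synthase, fell from 132 to 51.1 (-1.37 ± 0.08). All 6 passed in the same direction under each of the 4 scalings tried. This comparison addresses the effect of the endophyte-infected diet named in the series title, with day 14 in EI against day 11 in EF and every EI array in the separate number range.

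Other genes with large changes included Slc25a10, a mitochondrial dicarboxylate carrier, at least 12.2-fold higher in EI (n = 2 EI arrays with a value), and Dmkn, at least 2.51-fold higher. Negr1 passed through 1 array, with 1.26, 1.5 and 33.2 on the EI arrays. Among the falls, Ppan, a ribosome biogenesis factor, was at least 3.78-fold lower, Hnrnpul1, an RNA-binding protein, at least 3.51-fold, Carhsp1 at least 2.77-fold and Pdia5 at least 2.57-fold. Esr1, the estrogen receptor alpha, was at least 1.72-fold lower on its brighter probe, and its other probe gave a log2 change of 0.46. Probes of one gene also differed for Fos (-2.65 and 0.07 on the others), Pdia3 (0.44 and -0.23) and Fst, which encodes the activin-binding follistatin (1.01 ± 0.08, and -0.65 on the other).

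Of all 10177 probes, 315 were higher and 2138 lower in EI. The neuronal list, of genes not anticipated in this tissue, had 0 of 56 higher and 19 lower. Falls were therefore not particular to the groups below. By gene group, the immediate early genes had 0 of 24 members higher and 9 lower in EI, with Fos and the nuclear receptor Nr4a2 (80.3 in EF, 43.1 in EI; -0.90 ± 0.07) among them. Quantile normalization and cyclic loess each gave 2 higher and 6 lower, and 75th percentile scaling 2 and 5. Prostaglandin metabolism had 0 of 17 higher and 7 lower, 1 and 4 by quantile normalization and by cyclic loess, and 3 and 4 under 75th percentile scaling. The smallest p in this list belonged to Ptgds and then Ptgis, the prostacyclin synthase (8.97 to 3.69; -1.28 ± 0.13). Antioxidant and xenobiotic enzymes had 2 of 69 higher and 25 lower, 4 and 9 by quantile normalization, 5 and 9 by cyclic loess, and 7 and 9 under 75th percentile scaling. Gpx4, a lipid hydroperoxidase, was at least 1.8-fold lower and Gpx3, the plasma glutathione peroxidase, fell from 15.1 to 7.36 (-1.03 ± 0.10). Smooth muscle and vascular tone had 1 of 29 higher and 12 lower, 3 and 4 by quantile normalization and by cyclic loess, and 4 and 5 under 75th percentile scaling. Npr2, a natriuretic peptide receptor, fell from 20.6 to 9.06.

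Scaling to the 75th percentile moves all probes of an array alike, with the median change of all probes going from -0.14 to 0.45, so a balance that turns under it does not set a list apart from other genes. Relative to the median of the 6273 genes, which both of these scalings leave the same, the median change of a list ran from -0.34 for dopamine, serotonin and adrenergic signalling to 0.25 for the respiratory chain. By quantile normalization these were -0.09 and -0.01. Ribosomal proteins lay at -0.25, and at -0.39 by quantile normalization and -0.24 by cyclic loess. They had 1 of 26 higher and 13 lower, 5 and 10 by quantile normalization, and 10 and 5 under 75th percentile scaling. Rpl10a had the smallest p (128 to 37; -1.79 ± 0.08), and Rps20 was at least 3.92-fold lower. Heat shock and ER stress had 6 of 48 higher and 13 lower, but 10 higher and 3 lower by quantile normalization, 10 and 2 by cyclic loess, and 15 and 3 under 75th percentile scaling. Pdia3 was a rise and Hmox1, heme oxygenase, a fall (21.6 to 8.6) under all 4 scalings. Steroidogenesis had 1 of 29 higher and 8 lower, 0 and 1 by quantile normalization, and 4 and 1 under 75th percentile scaling. Hsd3b2, a hydroxysteroid dehydrogenase, was at least 1.85-fold lower. Hsd3b5 gave -0.70 under median scaling, and 0.13 by quantile normalization. The respiratory chain had 3 of 45 higher and 8 lower, 3 and 5 by quantile normalization, and 9 and 5 under 75th percentile scaling. Ndufb8, a complex I subunit, rose from 112 to 228 (1.03 ± 0.07), while Ndufb3 of the same complex fell from 18.8 to 5.15 (-1.86 ± 0.11).

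Further counts of higher and lower members in EI were 1 and 15 of 33 for dopamine, serotonin and adrenergic signalling, 0 and 19 of 56 for neuronal genes, 2 and 14 of 43 for extracellular matrix, 2 and 13 of 50 for immune cells, and 2 and 10 of 32 for luteal hormone and growth factor receptors. By quantile normalization these were 2 and 1, 5 and 9, 1 and 3, 4 and 5, and 3 and 4, and under 75th percentile scaling 4 and 1, 10 and 8, 7 and 4, 5 and 4, and 6 and 3. Drd4, a dopamine receptor, fell from 59 to 25.6 (-1.21 ± 0.09), and Mmp2, a gelatinase, from 155 to 64.1 (-1.27 ± 0.08, and -0.24 on its other probe). Endothelium had 1 and 8 of 37, cell cycle 1 and 9 of 34, apoptosis 1 and 9 of 25, follicle and oocyte 1 and 6 of 14, cholesterol synthesis 1 and 4 of 20, and blood and plasma proteins 0 and 4 of 9. By quantile normalization they had 1 and 2, 2 and 4, 1 and 3, 1 and 2, 2 and 2, and 0 and 2, and under 75th percentile scaling 7 and 4, 6 and 2, 2 and 2, 3 and 2, 5 and 2, and 0 and 1. Cyclic loess gave the neuronal list 8 and 7 and the blood and cholesterol lists 2 and 1 each. Adjusted over the list alone, the counts were 3 and 26 for antioxidant enzymes, 8 and 13 for heat shock, 4 and 10 for the respiratory chain, 1 and 14 for ribosomal proteins, 2 and 15 for extracellular matrix, 2 and 13 for smooth muscle, 1 and 9 for steroidogenesis, and unchanged for the other lists.

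Of 10177 probes, 2453 passed in EI vs EF, 315 higher and 2138 lower in EI. The split depended on the scaling, with 1651 higher and 786 lower under 75th percentile scaling, 619 and 888 by quantile normalization, and 698 and 701 by cyclic loess. The median log2 change of all probes was -0.14 under median scaling, 0.45 under 75th percentile scaling, -0.01 by quantile normalization and 0.02 by cyclic loess. Under all 4 scalings 796 probes passed in 1 direction, 249 higher and 547 lower, and they include 53 of the 61 named genes that passed. By quantile normalization the fold of 12 of the 61 was smaller by over 1.5 times, with log2 changes of -1.84 for Hs3st1, -1.19 for Ndufb3 and -0.49 for Ptgis (adjusted p = 0.019). The diets did not overlap at 35.8% of probes, where chance gives 10%. With camera, 0 of 19 lists passed, with 5 at an unadjusted p under 0.05 and a lowest adjusted p of 0.11 for ribosomal proteins (adjusted p = 0.53 with an estimated correlation, which also gave 0 lists). Without EF replicate 3, camera passed the ribosomal list at an adjusted p of 0.04. With fry, which asks whether a list moves and not whether it moves more than other genes, 18 lists passed, all lower in EI. The lowest adjusted p with fry, 3.1e-05, belonged to the neuronal list. Under 75th percentile scaling, which moves all lists together, 12 passed, all higher, by quantile normalization 1 higher and 3 lower, and by cyclic loess 1 higher and 2 lower. Diet, day, number of tissue samples ground and array number range cannot be told apart in this comparison.

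**Figure D2:**
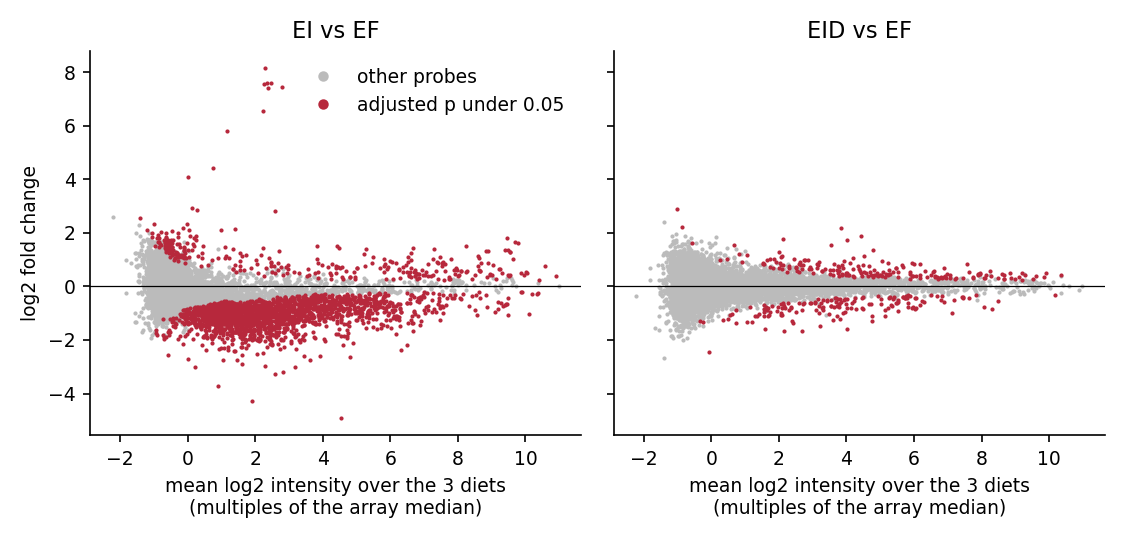
Log2 change of each probe against its mean log2 intensity (multiples of the array median) for EI vs EF (left) and EID vs EF (right), with probes past an adjusted p of 0.05 in red. Under median scaling 2138 of 2453 probes that passed in EI vs EF were lower, and under 75th percentile scaling 786 of 2437; in EID vs EF 158 of 346 were lower.

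Against EI, the EID arrays read Slc11a2, an iron transporter, higher by 2.95 ± 0.08 on the log2 scale (23.3 in EI, 181 in EID; limma adjusted p = 2e-13), while its other probe gave -0.12. Hs3st1 rose from 3.70 to 42.6 (3.53 ± 0.11) and Fos from 29.6 to 182 (2.62 ± 0.09, with 3.07 and 0.11 on the others). Eif4e3, a cap-binding protein, was at least 6.21-fold higher, Ppan at least 6.04-fold and Carhsp1 at least 4.74-fold. Ccl27 was at least 34.6-fold lower in EID, Slc25a10 at least 13.1-fold (n = 2 EI arrays with a value), and Grhpr fell from 21.9 to 3.05 (-2.85 ± 0.15). These 9 held under each of the 4 scalings. The comparison addresses what domperidone changed on the infected diet, on the same day after ovulation, but the arrays of the diets lie in separate number ranges.

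Of all 10177 probes, 2173 were higher and 302 lower in EID, and the neuronal list had 19 of 56 higher and 1 lower. Among groups, prostaglandin metabolism had 8 of 17 members higher in EID and 0 lower, with 3 and 0 by quantile normalization and by cyclic loess and 4 and 0 under 75th percentile scaling, and Ptgds rose from 51.1 to 115 (1.17 ± 0.08). Immediate early genes had 10 of 24 higher and 0 lower, 6 and 1 by quantile normalization, 5 and 2 by cyclic loess, and 6 and 2 under 75th percentile scaling. Antioxidant and xenobiotic enzymes had 26 of 69 higher and 5 lower, 11 and 5 by quantile normalization, 11 and 7 by cyclic loess, and 13 and 8 under 75th percentile scaling. Cyp2a1, a cytochrome P450, rose from 14.2 to 32 (1.17 ± 0.09). Follicle and oocyte genes had 5 of 14 higher and 1 lower, 3 and 2 by quantile normalization and by cyclic loess, and 4 and 3 under 75th percentile scaling, and Fst fell from 104 to 33.1 (-1.65 ± 0.08, and 1.04 on its other probe). Heat shock and ER stress had 11 of 48 higher and 8 lower under median scaling, but 2 higher and 10 lower by quantile normalization, 2 and 9 by cyclic loess, and 2 and 12 under 75th percentile scaling. Dnajc24, a co-chaperone, fell from 93.1 to 43.1 (-1.11 ± 0.08).

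Relative to the 6273 genes, the median change of a list in EID vs EI ran from -0.17 for extracellular matrix to 0.47 for prostaglandin metabolism, and by quantile normalization these were -0.12 and 0.28. Ribosomal proteins had 13 of 26 higher and 2 lower, 8 and 2 by quantile normalization, and 5 and 8 under 75th percentile scaling. Steroidogenesis had 9 of 29 higher and 0 lower, 2 and 0 by quantile normalization, and 3 and 3 under 75th percentile scaling. Cyp17a1, the enzyme of androgen synthesis, rose from 32 to 56.9 (0.83 ± 0.09), though its other probe gave -0.78. Cyp11a1 was at least 1.55-fold higher in EID under median scaling (fitted log2 change 1.01 ± 0.24, adjusted p = 0.0042), and by quantile normalization the change was 0.28 (adjusted p = 0.55). Dopamine, serotonin and adrenergic signalling had 13 of 33 higher and 0 lower, 2 and 1 by quantile normalization, and 2 and 3 under 75th percentile scaling, with Drd4 rising from 25.6 to 71.9 (1.49 ± 0.09). Neuronal genes had 19 and 1 of 56, respiratory chain 11 and 2 of 45, extracellular matrix 11 and 1 of 43, and immune cells 13 and 2 of 50. Endothelium had 9 and 1 of 37, luteal receptors 9 and 2 of 32, smooth muscle 9 and 0 of 29, and cell cycle 7 and 1 of 34. Apoptosis had 7 and 2 of 25, blood 5 and 0 of 9, and cholesterol synthesis 3 and 1 of 20. By quantile normalization these 11 groups gave 9 and 3, 4 and 3, 4 and 5, 6 and 2, 2 and 1, 4 and 6, 2 and 1, 3 and 3, 2 and 3, 0 and 0, and 2 and 1. Under 75th percentile scaling they gave 9 and 5, 4 and 5, 4 and 5, 4 and 8, 2 and 2, 3 and 7, 3 and 3, 3 and 7, 2 and 5, 1 and 1, and 1 and 4. Cyclic loess gave the neuronal list 5 and 5 and the blood list 0 and 2. Adjusted over the list alone, the counts were 12 and 0 for immediate early genes, 28 and 5 for antioxidant enzymes, 12 and 9 for heat shock, 14 and 2 for ribosomal proteins, 20 and 1 for neuronal genes and 15 and 3 for immune cells. They were 12 and 2 for extracellular matrix, 11 and 1 for endothelium, 10 and 0 for smooth muscle, 8 and 1 for cell cycle, 8 and 2 for apoptosis, and unchanged for the other lists.

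In EID vs EI, 2475 probes passed, 2173 higher and 302 lower in EID. The split was 822 and 1436 under 75th percentile scaling, 908 and 602 by quantile normalization, and 725 and 671 by cyclic loess. The median change of all probes was 0.15 under median scaling and -0.43 under 75th percentile scaling. Under all 4 scalings 817 probes passed in 1 direction, 580 higher and 237 lower, among them 51 of the 60 named genes that passed. By quantile normalization the fold of 16 of the 60 was smaller by over 1.5 times and of 1 larger, and Hs3st1 gave 2.77. The diets did not overlap at 37.5% of probes, where chance gives 10%. With camera, 0 of 19 lists passed, with 4 at an unadjusted p under 0.05 and a lowest adjusted p of 0.085, shared by prostaglandin metabolism and immediate early genes (adjusted p = 0.44 for both with an estimated correlation, again 0 lists). With fry 17 lists passed, all higher in EID, against 1 higher and 14 lower under 75th percentile scaling, 2 and 1 by quantile normalization, and 2 and 4 by cyclic loess. Without EI replicate 2, camera passed the prostaglandin list at an adjusted p of 0.034.

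Most of what separated EI from EF also separated it from EID. Of the 2453 probes that passed in EI vs EF, 1969 (80.3%) passed in EID vs EI the other way, such as Ccl27, Hs3st1 and Fos, and 14 passed in the same direction. By quantile normalization 1076 of 1507 (71.4%) did so. Sharing the EI arrays alone makes the changes of the comparisons oppose each other. Over all probes their correlation was -0.81, and -0.79 by quantile normalization, against -0.495 on average in 20 simulations of unchanged groups that share the EI arrays. These simulations held no EI difference. Any difference of the EI arrays alone, from diet or array range, makes the correlation more negative. The gap therefore restates that EI differs and cannot show that domperidone reversed a change. The EI arrays serve in both comparisons, and 3 arrays do not divide into separate sets for each. The Pearson correlation of array pairs over 2561 bright probes was 0.973 to 0.982 between EF and EID, 0.923 to 0.93 between EF and EI, and 0.925 to 0.931 between EI and EID. Within a diet it was 0.981 to 0.991 in EF, 0.986 to 0.988 in EI and 0.993 in EID. Over all probes the Spearman correlation of EI arrays with each other, 0.643 to 0.671, was no higher than with EF arrays (0.645 to 0.69) or EID arrays (0.643 to 0.689). It was 0.787 to 0.805 within EF, 0.807 to 0.812 within EID and 0.774 to 0.812 between EF and EID.

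**Figure D3:**
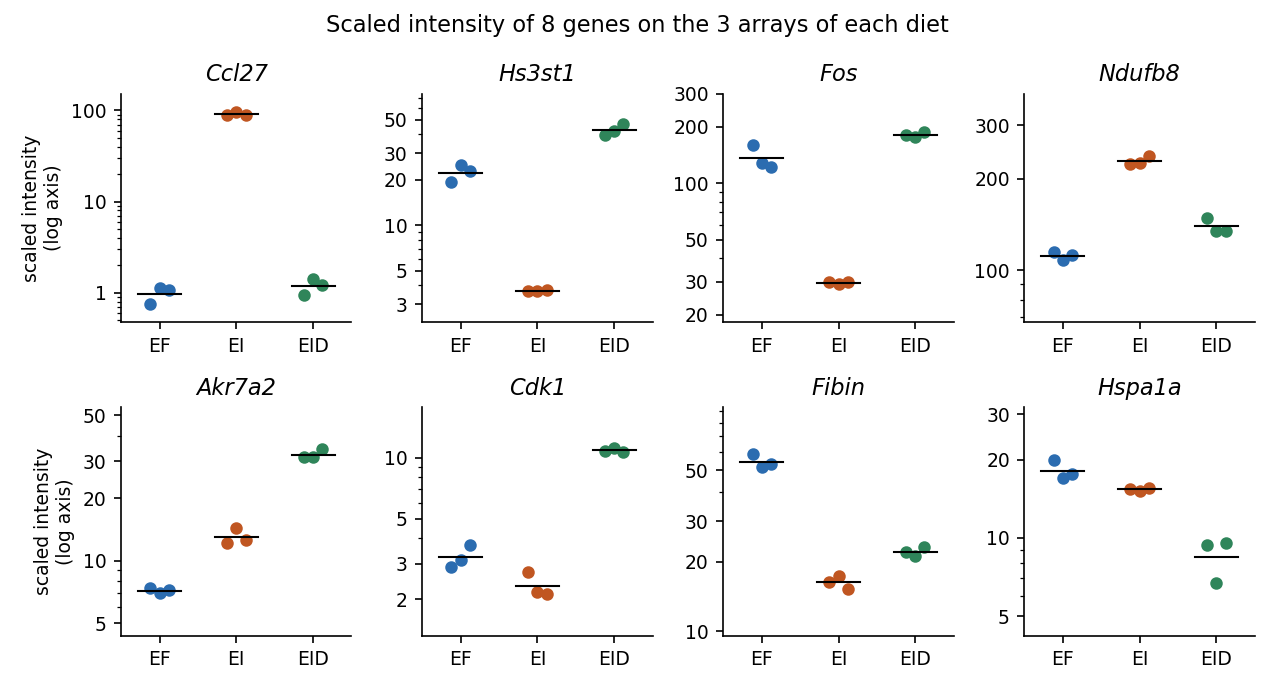
Scaled intensity (multiples of the array median, log axis) of 8 genes on the 3 arrays of each diet, with bars at the means. Ccl27 lies at 91.3 in EI and 0.97 in EF, and Akr7a2 at 32.4 in EID and 7.17 in EF.

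Against EF, the EID arrays read Akr7a2, an aldo-keto reductase that detoxifies aldehydes, higher by 2.18 ± 0.10 on the log2 scale (7.17 in EF, 32.4 in EID; limma adjusted p = 3.7e-09). Cdk1, the mitotic kinase, rose from 3.23 to 10.9 (1.75 ± 0.15), and Hsd17b2, which oxidizes estradiol, from 3.48 to 7.69 (1.14 ± 0.19). Fibin fell from 54.4 to 22.1 (-1.30 ± 0.09), and the apoptosis inhibitors Birc2 and Mcl1 fell from 20.5 to 8.91 (-1.20 ± 0.10) and from 23.1 to 11.7 (-0.98 ± 0.10). Acsl1, a fatty acid activating enzyme, was at least 2.67-fold lower. This comparison, infected seed with domperidone on day 14 against endophyte-free seed on day 11, lies within 1 array number range.

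Among the heat shock and ER stress genes, 0 of 48 rose and 5 fell in EID. Dnajc24 fell from 76 to 43.1 (-0.82 ± 0.08), Herpud1, an ER stress protein, from 71.1 to 42.1 (-0.76 ± 0.08), Hspa1a, an inducible heat shock protein, from 18.2 to 8.45 (-1.11 ± 0.13), and Eif2ak3, the ER stress kinase, from 19 to 12.1 (-0.65 ± 0.09). Adjusted over the list alone, 1 was higher and 7 lower. In steroidogenesis 2 of 29 rose and 0 fell. These were Hsd17b2 and Cyp17a1 (38.8 to 56.9; 0.55 ± 0.09), whose other probe gave -0.36, and Cyp11a1 gave 0.75 (adjusted p = 0.14). Ribosomal proteins had 1 of 26 higher, Rps6 (20.8 to 30.6), and 3 lower, including Rpl10a (128 to 78.9). Luteal hormone and growth factor receptors had 2 of 32 higher and 2 lower. Igfbp5, an IGF-binding protein, rose (0.66 ± 0.13, and -0.06 on its other probe) and Pgrmc1, a membrane progesterone receptor component, fell from 398 to 274 (-0.54 ± 0.07, and -0.16 on its other probe). Fst fell from 51.5 to 33.1 (-0.64 ± 0.08, and 0.39 on its other probe).

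In apoptosis 0 of 25 rose and 2 fell, Birc2 and Mcl1, and the other Birc2 probe gave 0.29. Antioxidant and xenobiotic enzymes had 3 of 69 higher and 2 lower, with Prdx4, a peroxiredoxin, falling from 81.3 to 44.9 (-0.86 ± 0.14). Cell cycle had 2 of 34 higher, Cdk1 and Pola2, and 2 lower, Ccng1 and Tyms. The respiratory chain had 1 of 45 higher, Ndufb8 (0.32 ± 0.07), and 2 lower, Ndufb3 (-0.54 ± 0.11) and Atp5pb (-0.48 ± 0.10). Neuronal genes had 0 of 56 higher and 2 lower, Gria4 and Kcna2. Follicle and oocyte had 1 of 14 higher, Cyp17a1, and 1 lower, Fst. Single members passed in prostaglandin metabolism (Ptger2, higher, 1 of 17), dopamine, serotonin and adrenergic signalling (Adra1d, higher, 1 of 33), endothelium (Arnt, higher, 1 of 37), immediate early genes (Fos, higher, 1 of 24), extracellular matrix (Col12a1, lower, 1 of 43), and immune cells (RT1-Bb, lower, 1 of 50, within the background on both diets). In cholesterol synthesis, smooth muscle and blood proteins 0 of 20, 0 of 29 and 0 of 9 members passed. Adjusted over the list alone, the counts were 4 higher and 2 lower for antioxidant enzymes, 0 and 3 for apoptosis, 2 and 0 for immediate early genes, and unchanged for the other lists apart from heat shock. The other probe gave -0.08 for Arnt, 1.64 for Ptger2, -0.09 for Ccng1 and -0.01 for Gria4. Adra1d, Pola2, Tyms and RT1-Bb did not pass by quantile normalization.

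In EID vs EF, 346 probes passed, 188 higher and 158 lower in EID, and under all 4 scalings 292 did, 155 higher and 137 lower, with 44 of the 52 named genes that passed. The diets did not overlap at 17.6% of probes, where chance gives 10%. With camera, 0 of 19 lists passed, with 1 at an unadjusted p under 0.05 and a lowest adjusted p of 0.49 for ribosomal proteins, 0 lists with an estimated correlation and 0 with fry. For ribosomal proteins the adjusted p with camera was 0.055 by quantile normalization and 0.066 by cyclic loess. With fry 3 lists passed as lower under each of these, ribosomal proteins (adjusted p = 0.0061 by quantile normalization), apoptosis (0.033) and heat shock and ER stress (0.033). The count rests on the variance trend, since without it 14 probes passed, and it fell to 191 at 1.5-fold and to 194 without EID replicate 3, 209 without EID replicate 1 and 228 without EID replicate 2. Diet with domperidone, day, and number of tissue samples ground cannot be told apart here.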

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

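Cyclic loess, quantile normalization with brighter probes, the limit to probes with 1 symbol, and 75th percentile scaling for lists, named genes and the overlap were chosen after seeing the data. For the probes that passed in EI vs EF and in EID vs EI, quantile normalization lowered the counts to 1507 and 1510 and cyclic loess to 1399 and 1396, and the probes passing the other way in EID vs EI fell to 1076 and 986. For these lower counts the cause was not tested. Of the 2453 and 2475 probes, 1150 and 1167 also passed in the same direction by quantile normalization. For EID vs EF the count of 346 became 14 without the variance trend (7 higher, 7 lower), where the cause was not tested, and 191 with a 1.5-fold threshold, which by construction passes fewer. Leaving out 1 array gave 194 to 372 there, with the lowest count without EID replicate 3 and the highest without EF replicate 1, and fewer arrays enter these fits. Under the other alternatives run, including a replicate block (2453, 2453 and 317, the numbers showing no pairing with correlations from -0.02 to 0.027), the counts stayed within 1.5 times. Leaving out 1 array gave 2199 to 2371 for EI vs EF and 2098 to 2328 for EID vs EI. For lists, fry in place of camera passed 18 in EI vs EF and 17 in EID vs EI, but 4 and 3 by quantile normalization and 3 and 6 by cyclic loess, and under 75th percentile scaling 12 and 15 with the direction turned in nearly all. With camera, leaving out 1 array gave 0 to 1 in each. The filter on dim probes removed 0 probes, so fitting without it was not run. Hsd3b5 in EI vs EF reversed to 0.13 by quantile normalization and 0.09 by cyclic loess, and Slc4a1, an anion exchanger of red cells, in EID vs EI reversed to -0.10 by cyclic loess, and the cause was not tested. Of the named genes that passed, 5 of 61 in EI vs EF, 4 of 60 in EID vs EI and 8 of 52 in EID vs EF did not pass by quantile normalization. On each array 16.1% to 24% of probes exceeded the background limit, while all 10177 were tested, so some that passed lay within it on both diets, such as RT1-Bb in EID vs EF.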

Other observations

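The splits of the arrays, the correlation of probe pairs in their EI difference and quantile normalization were planned, but the quantile counts were set against the explanations only after they were seen. The change by brightness, the ribosomal level, the empty cells, the probes without a symbol and the changes shared by EI and EID were examined after the result was seen. The level correlation of probe pairs was rebuilt after its first value was seen, and the EID difference was set beside the EI difference as a control only then.

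Some genes differed from EF in the same direction in both groups fed infected seed. Among the probes that passed in both EI vs EF and EID vs EF, 173 changed in the same direction, 55 higher and 118 lower, and 83 in opposite directions, with 159 and 60 by quantile normalization. Both comparisons use the same EF arrays, which by itself favours equal signs. Over all probes the changes of these comparisons correlated at 0.32, below the 0.50 on average in the 20 simulations of unchanged groups. These simulations held no EI difference, and a difference of the EI arrays alone lowers this correlation. It therefore cannot show whether the changes agree beyond sharing arrays. For the counts of probes that passed, how far sharing favours equal signs stays open, since the simulations held no changes of the size seen in EI. Under all 4 scalings 89 changed in the same direction, 42 higher and 47 lower. Fibin read 54.4 in EF, 16.4 in EI and 22.1 in EID, Strbp, an RNA-binding protein of spermatids, 9.85, 4.09 and 3.80, and Rpl10a 128, 37 and 78.9. Akr7a2 read 7.17 in EF, 13 in EI and 32.4 in EID, and Igfbp5 5.88, 8.35 and 9.29. These heifers shared the infected seed, the day after ovulation and the number of tissue samples ground, and the test cannot separate the 3.

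Marks that follow the EI arrays lay in the empty cells, counted over probes with and without a gene symbol, and in some bright runs of probes without one. At 98 probes all EF and EID arrays were empty and all EI arrays had values, and 11 of these read over 3 times the median on every EI array, the highest at 25.1 on average. At 21 probes the EI arrays alone were empty. Among neighbouring probes without a symbol, 8 runs of at least 5 probes (116 probes) read over 16 times the median in at least 1 diet, by a rule set after the values were seen. A run of 6 read 136 to 190 on every EI array and at most 2.32 on any other array, and a run of 8 averaged 1470 in EI, 548 in EF and 539 in EID. The other runs all averaged highest in EID, such as a run of 36 at 185 in EF, 208 in EI and 216 in EID. Of the 116 probes, 73 passed in EI vs EF, 71 in EID vs EI and 32 in EID vs EF, where 346 of all probes passed.

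The first pattern is that the EI arrays differ from both EF and EID arrays. Day after ovulation or number of tissue samples ground is argued against as the whole cause, since EI and EID share both and still gave 1510 probes by quantile normalization. An effect of the array number range remains open, because the EI differences of 2 bright probes of one gene correlated over 80 genes at 0.13, inside the -0.22 to 0.22 of random pairs, but the EID differences from EF, within 1 range, gave 0.19 inside -0.20 to 0.22 and so the test does not separate the sources. An effect of the infected seed that domperidone undid also remains open, with 1076 probes passing the other way by quantile normalization, and since the marks above follow EI alone, diet and array range cannot be told apart. Among the 10 splits of the 6 arrays of each comparison, 1 gave as many probes, the real one with 2453, 2475 and 346, against 0 in the highest other, and 10 splits are too few for a share under 0.05. Each other split puts arrays of both diets on both sides, so any difference between the diets adds to its spread. Its low count therefore does not decide whether the grouping arose by chance.

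The second pattern is that 87.2% of the probes that passed in EI vs EF were lower. A single scale factor per array is argued against as the whole of the EI difference, since it would move all probes alike. Probes at 4 to 16 times the median fell by more than probes over 16 times in all 9 pairs of an EI and an EF array, with a median gap of -0.40 (-0.48 to -0.27), against -0.11 to 0.02 in the 9 pairs of an EID and an EF array. The 5813 probes averaging under the array median rose in EI vs EF, with a median log2 change of 0.157. It was -0.462 at 1 to 2 times the median, -0.8 at 2 to 4, -0.768 at 4 to 16 and -0.365 over 16. In EID vs EF these medians ran from -0.0135 to 0.0688. The share of lower probes does depend on the scale factor, since 75th percentile scaling, which changes it alone, gave 32.3%. How far a scale factor is part of the cause stays open. A background or response that differs with brightness on the EI arrays, and an effect of the infected diet or a lower RNA signal from the tissue, stay open and were not tested. The lower share of 58.9% by quantile normalization and 50.1% by cyclic loess does not decide, because both methods centre the changes.

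The third pattern is that bright probes of one gene often differ in their changes. The EI difference had equal sign at 44 of 80 genes and the EID difference from EF at 40 of 80, and neither correlated beyond random pairs. Some probes agree, such as 2 of the 3 Fos probes at -2.19 and -2.65 in EI vs EF. Probe names that belong to other probes are argued against by the 26 ribosomal protein genes, whose mean log2 level of 3.88 lay above the highest of 10000 random lists, 2.42. Even so, 9 of these 26 averaged within the background. Whether some rat probes read little of the bovine transcript they are named for stays open, because the mean levels of 2 probes of one gene, which correlated over 742 genes at 0.065 within the -0.071 to 0.073 of random pairs, also depend on the affinity of each probe. Splicing or transcript variants that differ between probes stay open and were not tested. No biological explanation of the design was tested for this pattern.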
